A study of Arabidopsis thaliana with 11 samples.

How the data were processed

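Chromatin from whole Arabidopsis thaliana seedlings (ecotype Columbia) was immunoprecipitated with an antibody against the Flag epitope and sequenced. The series holds 11 samples. Of these, 8 carry a Flag-tagged form of the light-signalling transcription factor HY5 driven by the viral 35S promoter. HY5ox is the unmodified protein (3 libraries), HY5-VP16 carries an activation domain (3 libraries) and HY5-SRDX carries a repression domain (2 libraries). The other 3 samples are controls without a tagged protein, 2 from Columbia and 1 named for the hy5 mutant. Per the labels' protocols, seedlings spent 3 days in darkness at 21 °C and then 2.5 h in simulated white light of 100 µmol per square metre per second. The labels place the samples in 3 sets, each with its own control. Set 1 holds HY5ox replicate 1, HY5-VP16 replicates 1 and 2 and both HY5-SRDX libraries. Set 2 holds HY5ox replicate 2, and set 3 holds HY5ox replicate 3 and HY5-VP16 replicate 3.

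Per the submitters' processing notes, CASAVA 1.8.2, Bowtie2 2.3.0 and HOMER 4.9.1 were used with the TAIR10 genome build. Per the file headers, peaks were called in each library separately with HOMER findPeaks in its transcription factor mode, at a false discovery rate of 0.001. A peak had to exceed the control of its set by 3-fold with a Poisson p of 0.0001 and the surrounding 10 kb by 2-fold with a Poisson p of 0.001. The signal of a peak, as deposited, is its tag count scaled to 10 M tags. For the fold, the control tags were scaled to the immunoprecipitated library in 7 libraries, and in HY5-VP16 replicate 3 the peak tags were scaled to the control, per the file headers. The deposited score is the caller's own value for each peak, and the deposited fold is the ratio of a peak's tags to those of the control or of the local region. These are the authors' values, and they were used only to describe and rank peaks within 1 list. All peaks of a library have 1 width, between 167 and 301 bp, set by the caller. The authors also assigned peaks to genes, either to a promoter reaching 2000 bp upstream of the start site or to the gene body, and deposited a gene list for each library. A further deposited table merges peaks found in all libraries. How the authors chose the annotation behind these assignments is not given in the sources used here.

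The gene lists were used as deposited, so that a gene is either listed (bound) or not listed in a library. A peak that the authors assigned to both a promoter and a gene body was counted as a promoter peak. Names, gene types and gene lengths came from a RefSeq table of assembly TAIR10.1, whose coordinates were not used. Of 25262 gene identifiers listed in any library, 24902 matched that table, which holds 37899 nuclear genes, 27444 of them protein-coding. Peaks of different libraries were called shared when they overlapped by at least 1 bp. Confidence intervals for shares of peaks are 95% Wilson intervals and cover counting error only. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

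The library was the unit of every test between constructs. Peak numbers, gene numbers and shares of peaks were compared with two-sided exact permutation tests, whose smallest possible p is 0.1 for 3 libraries against 3 and for 3 against 2. Likeness of gene lists was measured with the Jaccard index, the genes shared by a pair of libraries over the genes in either. The mean index within constructs minus the mean between constructs was tested one-sided against all 280 ways to divide the libraries into groups of 3, 3 and 2. The same was done for the 3 sets, with 168 ways. The genes of a construct are those listed in every one of its libraries. Overlap of these sets is given as an odds ratio over the annotated genes with the overlap of independent lists. Because the two-sided Fisher p was too small to be represented, the log10 of the upper hypergeometric tail is given in its place. Construct-specific genes are those in every library of 1 construct and in none of another, and their number was set beside that of every other division of the same libraries.

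The 12 gene lists, with 177 members, were tested with two-sided Fisher's exact tests against the other annotated genes, with Benjamini-Hochberg adjustment over 144 tests (12 lists in 12 target sets) and a threshold of 0.05. Odds ratios of lists were computed after adding 0.5 to each cell. They were tested again with protein-coding genes alone as background and against 10000 random lists matched on gene length. For 2 members the reference table does not give the symbol at the locus used. The genes named in the text follow a rule. It takes the members of the light signalling, BBX and flavonoid lists bound in all 8 libraries, up to 4 examples of each other list by number of libraries and then by rank, and HY5. It also takes the 10 genes with the best mean rank of their strongest peak in all HY5ox libraries and in all 8, and up to 5 genes for each ordered pair of constructs. Tests, samples, gene lists, the naming rule and most alternatives were fixed before the data were examined. The classes of exon, intron and intergenic region foreseen for peak positions were replaced by the promoter and gene body classes that the tables hold. A search for DNA motifs in peaks needs a genome sequence and was not analysed here.

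The test of likeness within and between constructs was run on simulated data, 20 draws over 37899 genes with 1000 genes planted per construct. With planted genes listed strongly, the Jaccard index passed the threshold in 0 of 20 draws (p between 0.1 and 0.118). The reason was not tested. The share of the shorter list that is shared and the odds ratio, both alternatives, passed in 20 of 20. With weak planting the Jaccard index and the share of the shorter list passed in 0 of 20 draws and the odds ratio in 7 of 20. With nothing planted, none of these 3 measures passed in any of the 20 draws. The list test called the planted list in 20 of 20 draws for each construct when planting was strong, and in 3 or 4 of 20 when it was weak. On average 53.4% to 57.2% of strongly planted genes were found as construct-specific, and 0.44% to 8.52% of weakly planted ones. The overlap step was checked directly on 2700 peak comparisons, with 0 disagreements.

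Total tags per library ranged from 11.5 to 56.0 M. The alternatives were leaving out each library, the upper part of each peak list by score, equal numbers of top peaks (2958 per library), assignment to the nearest start site within 3000 bp, and other measures of likeness and overlap. Other backgrounds for the gene lists, an own promoter definition of 1000 bp and blocks for set and replicate number were also tried. The control libraries have no peak list of their own and enter only through the authors' peak calls.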

Results

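Binding of HY5, a basic leucine zipper protein that drives seedling greening in light, was profiled in 8 Flag immunoprecipitation libraries from seedlings moved from darkness to light for 2.5 h. The libraries comprised 3 of HY5ox, 3 of HY5-VP16 and 2 of HY5-SRDX. Nothing in the labels says that libraries of a construct came from separate lines or cultures, so p-values measure the spread between these libraries, which may be technical. Depth was 22.3 ± 16.2 M tags in HY5ox (SD, n = 3), 30.5 ± 22.2 M tags in HY5-VP16 (n = 3) and 18.2 ± 3.00 M tags in HY5-SRDX (n = 2). The deepest libraries were those of set 3, HY5-VP16 replicate 3 with 56.0 M tags and HY5ox replicate 3 with 40.9 M tags.

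HY5-bound regions were numerous in all constructs. HY5ox libraries listed 10055 ± 2755 peaks and 11479 ± 2670 target genes (SD, n = 3). HY5-VP16 libraries listed 8616 ± 5266 peaks and 9031 ± 4878 genes (n = 3), and HY5-SRDX libraries 16590.5 ± 5542 peaks and 14170.0 ± 3165 genes (n = 2). The single libraries ranged from 2958 peaks in HY5-VP16 replicate 3 to 20509 in HY5-SRDX replicate 1. HY5-VP16 replicate 3 also had the smallest share of its tags in peaks, 1.83%, against 5.94% to 10.1% in the other 7 libraries. HY5ox exceeded HY5-VP16 by 1439 peaks, less than the spread between replicates (exact permutation p = 0.7, two-sided), and without HY5-VP16 replicate 3 the difference became -1390. Without HY5ox replicate 1 or 2 or HY5-VP16 replicate 2 it was 243.3, 2945 or 3819. HY5-SRDX libraries listed more peaks than HY5ox, with a difference of -6536 for HY5ox minus HY5-SRDX (exact permutation p = 0.1, the smallest possible). The difference of HY5-VP16 minus HY5-SRDX was -7975 (exact permutation p = 0.3). Without HY5-SRDX replicate 1 these 2 differences became -2617 and -4056, without HY5-SRDX replicate 2 the first became -10454, and without HY5-VP16 replicate 3 the second became -5146.

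**Figure D1:**
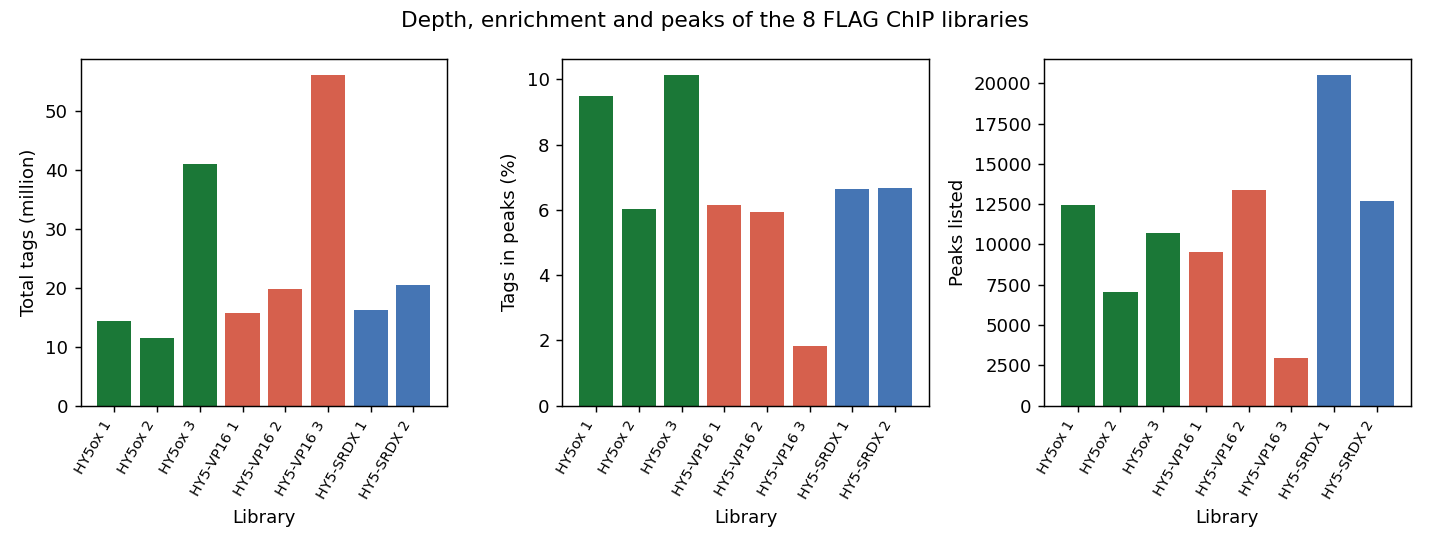
Bars give the total tags (M), the share of tags in peaks (%) and the number of peaks listed for each of the 8 libraries, coloured by construct. HY5-VP16 replicate 3 is the deepest library with the fewest peaks (2958), and HY5-SRDX replicate 1 lists the most (20509).

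Most peaks lay in promoters, here the 2000 bp upstream of a start site. The promoter share was 80.4% ± 1.60 in HY5ox (SD, n = 3), 76.1% ± 4.58 in HY5-VP16 (n = 3) and 61.1% ± 13.9 in HY5-SRDX (n = 2). HY5-SRDX replicate 1 had 51.3% of its peaks in promoters (95% interval 50.6% to 52.0%) and 30.3% in gene bodies, and HY5-SRDX replicate 2 had 71.0% and 16.01%. The gene body share of HY5ox was 9.31% ± 1.27 (n = 3). The median distance of peaks to a start site was 239 to 284 bp in HY5ox, 312 to 463 bp in HY5-VP16, 568 bp in HY5-SRDX replicate 2 and 1087 bp in HY5-SRDX replicate 1. HY5ox exceeded HY5-SRDX by 19.3 percentage points of promoter peaks (exact permutation p = 0.1, the smallest possible) and HY5-VP16 by 4.32 points (exact permutation p = 0.1). HY5-VP16 exceeded HY5-SRDX by 15.01 points (exact permutation p = 0.2). Without HY5-SRDX replicate 1 the gaps of HY5ox and HY5-VP16 over HY5-SRDX were 9.49 and 5.16 points, and without HY5-SRDX replicate 2 they were 29.2 and 24.9. Without HY5-VP16 replicate 2 the gap of HY5ox over HY5-VP16 was 1.68 points. Within set 1, the only set with all constructs, HY5ox replicate 1 had 80.1% of peaks in promoters. The HY5-VP16 libraries had 78.8% and 70.8%, and the HY5-SRDX libraries the shares above. With an own definition, a peak centre within 1000 bp upstream, the shares were lower. They were 57.5% to 62.3% in HY5ox, 48.79% to 58.65% in HY5-VP16, and 27.6% and 48.86% in HY5-SRDX replicates 1 and 2.

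The HY5 gene itself (AT5G11260, chromosome 5, 3593381 to 3594992, minus strand, TAIR10) carried a promoter peak in 8 of 8 libraries. Its centre lay between -24 and -80 bp relative to the start site. This peak ranked 1 or 2 of all peaks in the HY5-VP16 libraries, 18, 35 and 21 in the HY5ox libraries, and 34 and 19 in the HY5-SRDX libraries. In the authors' values it held 5.41 to 17.8 times the control tags. A second peak, inside the gene between 585 and 925 bp downstream of the start site, was listed in 6 of 8 libraries. HY5ox replicates 2 and 3 did not list it. The controls that these values rest on were Columbia seedlings in sets 1 and 3 and the sample named for the hy5 mutant in set 2.

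**Figure D2:**
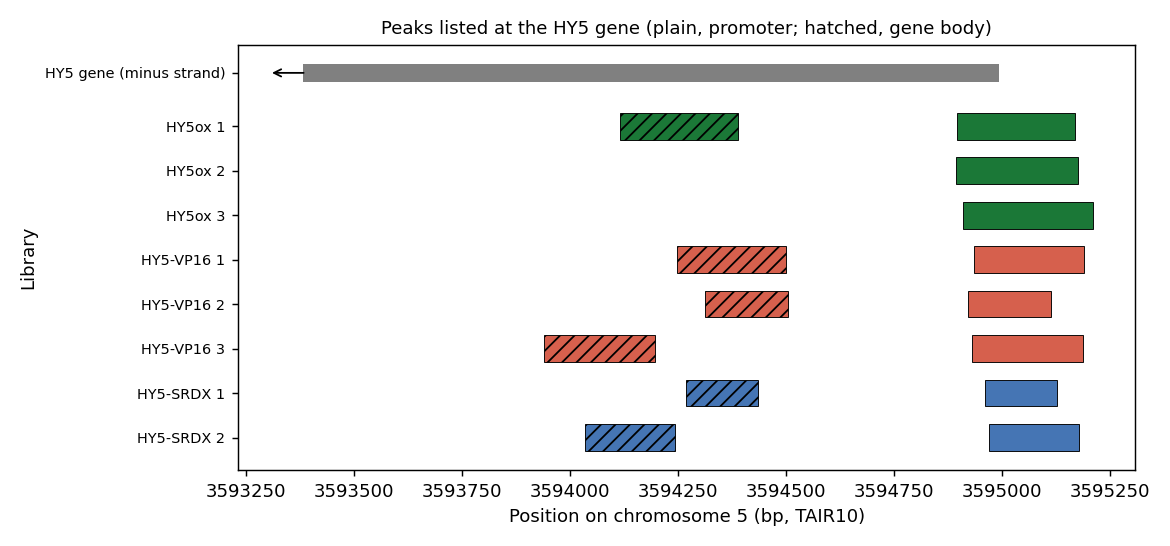
Position on chromosome 5 (bp, TAIR10) of the HY5 gene (grey, minus strand) and of the peaks listed there in each of the 8 libraries, plain for promoter and hatched for gene body. The promoter peak is present in 8 of 8 libraries and the gene body peak in 6.

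A core of genes was listed in each library of the 3 constructs. All 8 libraries listed 1913 genes, where independent lists of these lengths would share 1.09. Among protein-coding genes the count was 1805 against 6.18. These lists are not independent in their controls, since 5 libraries share the control of set 1 and 2 that of set 3. The authors' merged table held 981 peaks and 1272 genes found in all libraries, and 1202 of these genes were among the 1913. Without HY5-VP16 replicate 3 the count rose to 3192. The core was led by PP2CA (AT3G11410), a phosphatase that restrains abscisic acid signalling, whose strongest peak had a mean percentile rank of 0.119 (0 being the strongest) and 18.9 to 40.5 times the control tags. CPC (AT2G46410), a regulator of root hair and trichome patterning, followed with a mean rank of 0.123. SIG5 (AT5G24120), a light-induced sigma factor of plastid transcription, had a mean rank of 0.140, HY5 had 0.152, and the ubiquitin-conjugating enzyme gene UBC32 (AT3G17000) had 0.244. The clock gene GI (AT1G22770) had a mean rank of 0.248 and 11.01 to 48.4 times the control tags. The AT2G30032 locus ranked at 0.313. Because 33.8% to 43.5% of assigned peaks went to several genes, some of these share 1 region. SIG5 shared a peak with AT5G24130, CPC with AT2G46420, and UBC32 with AT3G16990. Among the 10 genes that led the HY5ox libraries, those listed in all 8 libraries but not among the 10 that led all 8 were ATL5 (AT3G62690, a ring finger protein gene), CYP86A4 (AT1G01600) and AT4G37240, with mean ranks of 7.54, 4.01 and 5.97. PUP4 (AT1G30840) was listed in 7 of 8.

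Circadian clock genes had the largest share bound of the 12 lists in HY5ox, in HY5-SRDX and in all 8 libraries, and in HY5-VP16 photoprotection genes had a larger one. HY5ox consensus genes included 14 of 15 (93.3%, against 17.9% of other genes, log2 odds ratio 5.47, adjusted p = 3.2e-08 by Fisher's exact test). HY5-SRDX included 14 of 15 (log2 odds ratio 5.28), HY5-VP16 11 of 15 (4.86), and all 8 libraries 11 of 15 (5.63, adjusted p = 6.75e-10 by Fisher's exact test). PRR9 (AT2G46790) had its strongest peak on chromosome 2 at 19232316 to 19232482, with a mean rank of 2.12. TOC1 (AT5G61380) and the evening gene LUX (AT3G46640) had mean ranks of 3.13 and 3.41, and the strongest peak of GI, PRR9, TOC1 and LUX lay in the promoter in 8 of 8 libraries. The list was called in each of these sets with protein-coding genes alone as background and against length-matched random lists as well.

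Light signalling genes were bound in all constructs. HY5ox consensus genes included 16 of 21 (76.2%, log2 odds ratio 3.78, adjusted p = 1.67e-07 by Fisher's exact test), HY5-VP16 11 of 21 (3.63), HY5-SRDX 13 of 21 (2.68, adjusted p = 0.000172 by Fisher's exact test) and all 8 libraries 10 of 21 (4.14). The 10 were the phytochrome genes PHYA and PHYB, the repressors COP1, SPA1 and SPA3, the feedback genes RUP1 and RUP2, HFR1, FHL and HY5. SPA1 (AT2G46340) had a mean rank of 1.16 with 5.55 to 19.99 times the control tags, HFR1 9.15 and COP1 9.79. At the other end, FHL had a mean rank of 44.6. The BBX list of B-box zinc finger genes was called in HY5ox (10 of 17, log2 odds ratio 2.68), HY5-VP16 (5 of 17, 2.31, adjusted p = 0.0198 by Fisher's exact test), HY5-SRDX (9 of 17, 2.17) and all 8 libraries (5 of 17, 3.09, adjusted p = 0.00351). The 5 were BBX4, BBX19, BBX24, BBX28 and BBX29, of which BBX28 (AT4G27310) ranked best with a mean of 3.04. With protein-coding genes as background the adjusted p of the BBX list was 0.0713 in HY5-VP16 and 0.0608 in HY5-SRDX by Fisher's exact test. Without HY5-SRDX replicate 2 the BBX list was not called in HY5-SRDX (log2 odds ratio 1.25, adjusted p = 0.127 by Fisher's exact test).

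Flavonoid and anthocyanin genes were called in HY5ox (11 of 20, log2 odds ratio 2.47, adjusted p = 0.000834 by Fisher's exact test) and HY5-VP16 (8 of 20, 2.94, adjusted p = 0.000443). In HY5-SRDX 6 of 20 were bound (0.85, adjusted p = 0.355 by Fisher's exact test). In all 8 libraries 4 of 20 were bound (2.40, adjusted p = 0.0292, and 0.0872 with protein-coding background, by Fisher's exact test). They were the flavonol regulator MYB11 (mean rank 5.46), the enzyme genes FLS1 (15.4) and F3H (20.2), and DFR (44.0), the entry to anthocyanins. CHS, the first enzyme of the pathway and chosen after its values were seen, was listed in 6 of 8 libraries with a mean rank of 23.2. Photoprotection and ultraviolet response genes were called in HY5ox and HY5-VP16, with 5 of 6 bound in each (log2 odds ratios 4.07 and 5.37, adjusted p = 0.00325 and 0.00012 by Fisher's exact test). In HY5-SRDX 2 of 6 were bound (1.16, adjusted p = 0.441 by Fisher's exact test). SIG5 and the photolyase gene UVR3 (AT3G15620, mean rank 7.75) were in all 8, and ELIP1 and the photolyase gene PHR1 in 7 of 8. Over all libraries, the flavonoid call ended without HY5-VP16 replicate 3 (1.60, adjusted p = 0.123 by Fisher's exact test), and the photoprotection list became called without HY5-SRDX replicate 1 or 2 (3.88 and 4.11, adjusted p = 0.011 and 0.00788 by Fisher's exact test).

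Other lists were called in some target sets. Hormone genes were called in HY5ox (7 of 14, log2 odds ratio 2.19) and HY5-VP16 (6 of 14, 3.11), with ABI5 and ERF11 in all 8 libraries and DWF4 and GA2OX1 in 7. With protein-coding background the hormone adjusted p in HY5ox was 0.0691 by Fisher's exact test. Nutrient genes were called in HY5-SRDX (8 of 12, 2.93, adjusted p = 0.00204 by Fisher's exact test), with APR2 and SULTR1;2 in all 8 libraries and NRT1.1 and NRT2.1 in 6. Against length-matched lists the nutrient adjusted p was 0.0819. Pigment and chloroplast genes were called in HY5-VP16 (5 of 15, 2.56) and bound in 5 of 15 in HY5ox and HY5-SRDX. CAO was listed in all 8 libraries, and PSY, CHLG and CHLH in 7. The pigment list in HY5-VP16 had an adjusted p of 0.135 against length-matched random lists. Antenna and Rubisco genes were not called in any construct (6, 0 and 3 of 18 in HY5ox, HY5-VP16 and HY5-SRDX). RBCS1A was listed in 7 of 8 libraries, and LHCB6, LHCB4.2 and LHCA4 in 6. Genes of shade and elongation growth were not called either (5, 0 and 4 of 13), with IAA19, PIL1 and YUC9 in 6 libraries and ATHB2 in 5. In single HY5ox libraries the shade list was called in replicates 1 and 3 (10 and 9 of 13, adjusted p = 0.00797 and 0.0139 by Fisher's exact test) and the antenna list in replicates 2 and 3 (9 and 11 of 18, adjusted p = 0.0186 and 0.0207). With protein-coding background these 4 adjusted p were 0.0999 or more by Fisher's exact test. Several calls in this group rest on 1 library. Without HY5ox replicate 1 the shade, pigment and antenna lists became called in HY5ox (log2 odds ratios 1.84, 1.87 and 1.75), and without HY5ox replicate 2 the shade and nutrient lists (2.09 and 1.91). In HY5-SRDX the shade and hormone lists became called without replicate 1 (1.78 and 1.94). Without replicate 2 the pigment list became called (1.78) and the nutrient call ended (1.86, adjusted p = 0.0626 by Fisher's exact test). Over all libraries the hormone list became called without HY5-SRDX replicate 1 (2.65).

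The remaining lists served for comparison. Housekeeping genes, included as highly expressed loci, were called in HY5ox and HY5-SRDX (6 of 11 in each, log2 odds ratios 2.435 and 2.25, adjusted p = 0.0149 and 0.0226 by Fisher's exact test). They were also called in all 8 libraries (3 of 11, 2.99, adjusted p = 0.0286 by Fisher's exact test). With protein-coding background these adjusted p became 0.066, 0.0956 and 0.0742. The log2 odds ratio of the flavonoid list was no higher in all 8 libraries (2.40) and about the same in HY5ox (2.47). The HY5-SRDX call ended without HY5-SRDX replicate 2 (log2 odds ratio 1.70, adjusted p = 0.101 by Fisher's exact test), and in HY5-VP16 the list became called without HY5-VP16 replicate 3 (3.17). ACT2, GAPC1 and UBQ10 were listed in all 8 libraries and ACT7 in 7. Seed and flower genes, which are little used in seedlings, were not called in any construct. HY5ox libraries listed 2.67 ± 0.577 of the 15 (SD, n = 3), HY5-VP16 2.33 ± 1.53 (n = 3) and HY5-SRDX 7.5 ± 0.707 (n = 2). OLEO1 was listed in 7 libraries, CRC in 4, and CRA1 and AG in 3. In all, 7 of 12 lists were called in HY5ox, 7 in HY5-VP16, 5 in HY5-SRDX and 5 in all 8 libraries, and with protein-coding background 5, 6, 3 and 3. Leaving out HY5-SRDX replicate 2 lowered the HY5-SRDX count to 3, and leaving out HY5ox replicate 1 or 2 raised the HY5ox count to 10 or 9. The share of each list bound in excess of other genes was compared between constructs, and the 36 differences had adjusted p of 0.4 or more by exact permutation tests whose smallest unadjusted p is 0.1.

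**Figure D3:**
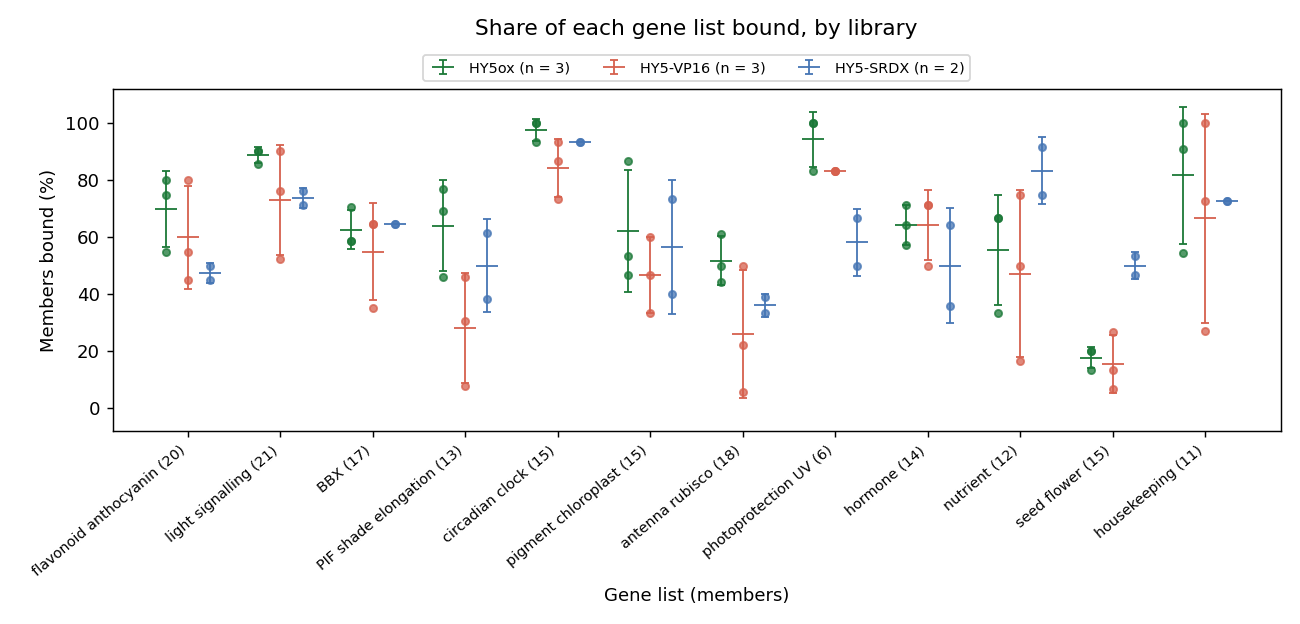
Share of the members of each gene list bound (%) in each library (points), with the mean (bar) and SD for HY5ox (n = 3), HY5-VP16 (n = 3) and HY5-SRDX (n = 2). Circadian clock genes are bound in 11 to 15 of 15 cases per library, and seed and flower genes in 1 to 8 of 15.

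Whether the added domains redirected HY5 was addressed by comparing gene lists within and between constructs. For HY5ox and HY5-VP16 the mean Jaccard index was 0.47 within constructs and 0.459 between them, a difference of 0.0105 (exact permutation p = 0.4, one-sided, smallest possible 0.1). For HY5ox and HY5-SRDX the indices were 0.523 and 0.399 (difference 0.124, exact permutation p = 0.1, one-sided), and for HY5-VP16 and HY5-SRDX 0.367 and 0.343 (0.0237, exact permutation p = 0.4, one-sided). The pairs depend on the measure too. By the share of the shorter list the differences were 3.50, 15.6 and 12.3 percentage points in the same order, each at the smallest possible exact permutation p of 0.1. By the log2 odds ratio they were -0.28, 1.79 and 1.44 (exact permutation p = 0.5, 0.1 and 0.1). Over all constructs the index was 0.455 within and 0.409 between, a difference of 0.0467 (exact permutation p = 0.0964, one-sided, 280 divisions). Grouped by set it was 0.446 within and 0.404 between (0.0416, exact permutation p = 0.286, one-sided, 168 divisions). The construct result rests on single libraries. Without HY5ox replicate 1, 2 or 3 the difference was 0.0125, 0.0123 or -0.00194 (exact permutation p = 0.381, 0.333 and 0.467), without HY5-SRDX replicate 1 or 2 it was 0.0209 or 0.0709 (exact permutation p = 0.214 and 0.171), and without HY5-VP16 replicate 1, 2 or 3 it was 0.0868, 0.0948 or 0.0698 (exact permutation p = 0.0381, 0.019 and 0.019). In set 1 alone it was -0.00945 (exact permutation p = 0.533), in a test with too few libraries to pass the threshold. In simulated data for this comparison this form of the Jaccard test found strong planted differences in 0 of 20 draws. Its exact permutation p was 0.1 to 0.118 with strong planting and 0.629 to 0.768 with nothing planted. That the main test did not pass is thus no evidence that the constructs were alike. Other measures of likeness within minus between constructs passed the threshold. The difference was 0.0949 for the share of the shorter list (exact permutation p = 0.00357), 0.143 for equal numbers of top peaks (exact permutation p = 0.00714) and 0.0914 for the upper part of peaks by score (exact permutation p = 0.0179). For shared peaks it was 0.0954 to 0.109 (exact permutation p = 0.0107 to 0.0214). The log2 odds ratio gave 0.80 (exact permutation p = 0.111). With blocks for set or replicate number, added after the data were seen, its exact permutation p was 0.0167 or 0.0278. The answer for the 8 libraries thus depends on the measure and, for the log2 odds ratio, on the block.

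**Figure D4:**
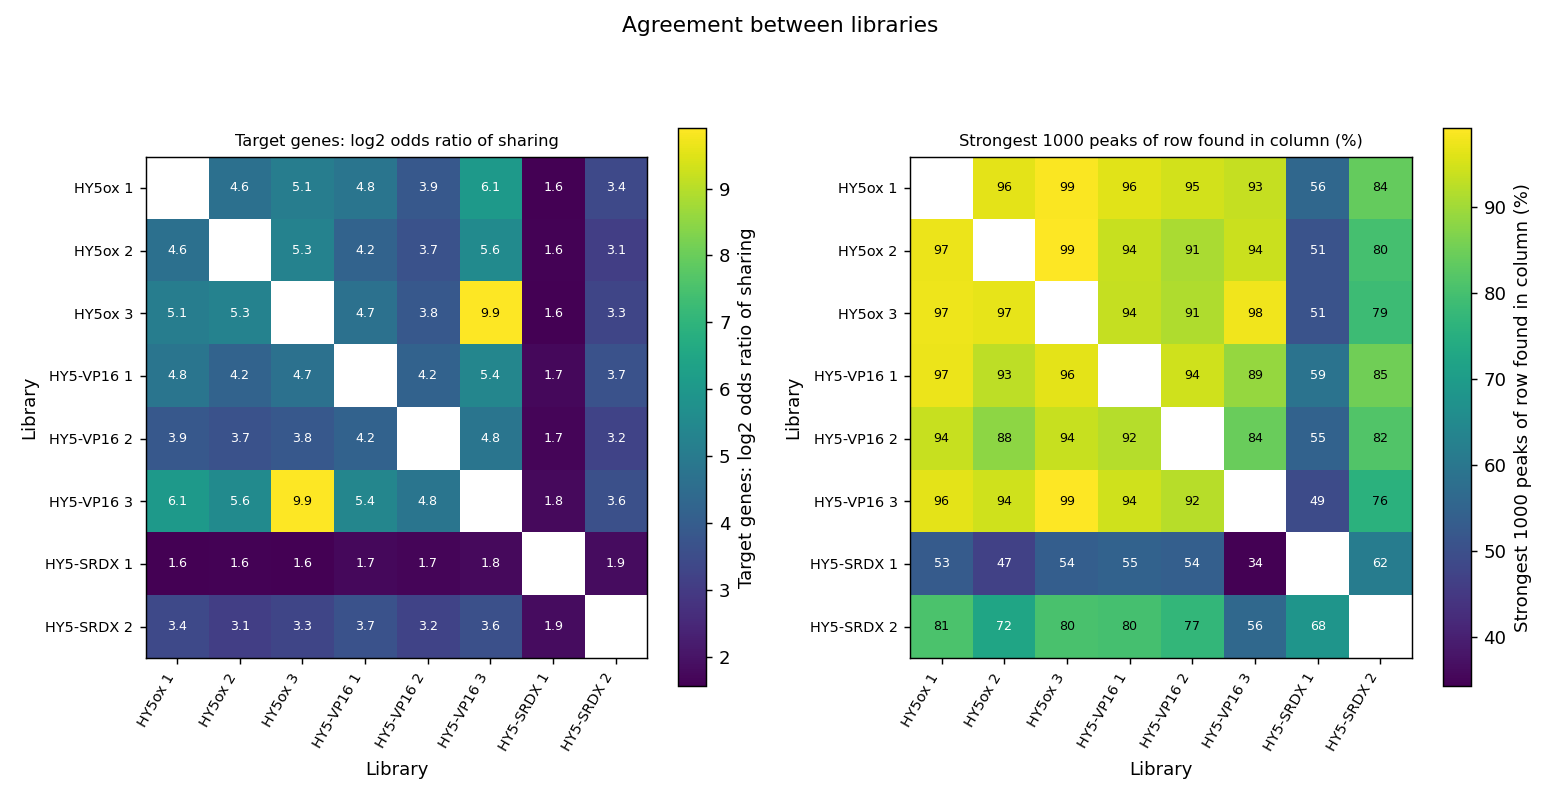
For each pair of the 8 libraries, the log2 odds ratio of shared target genes (left) and the share of the 1000 strongest peaks of the library on the vertical axis found in the library on the horizontal axis (right, %). HY5-SRDX replicate 1 has the lowest values, and HY5ox replicate 3 with HY5-VP16 replicate 3 has the highest odds ratio (9.90).

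In HY5ox libraries a median of 93.5% to 94.6% of the 1000 strongest peaks were found in another library, in HY5-VP16 libraries 88.2% to 94.3%, in HY5-SRDX replicate 2 77.2% and in HY5-SRDX replicate 1 53.6%. Genes in every library of a construct numbered 6907 for HY5ox, 3145 for HY5-VP16 and 7646 for HY5-SRDX. Without HY5-VP16 replicate 3 the HY5-VP16 set held 8183, and with 1 library left HY5-SRDX held 11932 or 16408. HY5ox and HY5-VP16 shared 2877 genes, of which 2821 are annotated against 553.7 for independent lists (log2 odds ratio 6.37, log10 of the tail probability -1981), or 91.4% of the smaller set. HY5ox and HY5-SRDX shared 3739 (3683 annotated against 1356, log2 odds ratio 3.05, log10 tail probability -1111), and HY5-VP16 and HY5-SRDX 2053 (2007 against 614.8, 3.30, -724.8). Without HY5-SRDX replicate 2 the last 2 log2 odds ratios fell to 1.70 and 1.96. With single libraries left out, that of HY5ox and HY5-VP16 ranged from 4.898 to 8.492. By definition the HY5-VP16 set lies within the 3643 genes of HY5-VP16 replicate 3, of which 3631 were in HY5ox replicate 3. The 91.4% and the 6.37 thus rest in part on that HY5-VP16 library. Libraries called against the same control can share calls for that reason. Between libraries of different sets the log2 odds ratios were 4.63, 2.99 and 3.02. These do not use all libraries of the full sets, so the gap to the values above does not measure what shared controls add. Part of the excess in the full sets may come from shared controls, which was not separated from the choice of libraries.

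In every HY5ox library and in no HY5-VP16 library were 416 genes, and the reverse held for 0 genes, which was 386 without HY5-VP16 replicate 3, 13 without HY5ox replicate 3 and 4 without HY5-VP16 replicate 1. The 416 became 1056 without HY5ox replicate 2, 844 without HY5-VP16 replicate 1 and 948 without HY5-VP16 replicate 2. The best ranked of the 416 were AT3G53830 (mean rank 9.60, 4.33 to 8.19 times the control tags) and AT2G28730 (11.9). Next came AT1G77932, AT1G77940 and the MADS box gene AGL67 (AT1G77950), which share 1 peak on chromosome 1 at 29305205 to 29305477. Of the 10 divisions of these 6 libraries, 3 gave at least 416 genes, the real one included, with 675 as the highest other. Grouping by set, with set 1 against sets 2 and 3, gave 535.

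Counts against HY5-SRDX rest on 2 libraries of that construct, and fewer libraries give more genes by construction, so they are not compared with the 416 above. In every HY5ox library and neither HY5-SRDX library were 881 genes, led by AT2G45610 (mean rank 0.533), AT2G25530 (1.23), the phenylpropanoid gene 4CL1 (AT1G51680, 2.09), PPR2 (3.92) and AT5G09755 (18.1). In both HY5-SRDX libraries and no HY5ox library were 1325 genes, among them HCF153 (AT4G31560, 3.93), AT1G78850 (5.95), EMB2758 (9.17), the histone deacetylase gene HDT4 (16.9) and AT3G12830 (28.6). The sum of 2206 was higher than in the other 9 of 10 divisions of the 5 libraries, whose highest was 953. In every HY5-VP16 library and neither HY5-SRDX library were 234 genes, including AT2G45610, AT2G25530, the phosphate carrier gene PHT3;3 (2.04), DCF (1.99) and ELIP2 (AT4G14690, an early light-induced chlorophyll-binding protein gene, 7.31). The reverse held for 1386 genes, including AT5G60260, AT5G60270, AT5G51190, AT5G67455 and AT3G15356. The sum of 1620 was also higher than in the other divisions, whose highest was 1492. With 10 divisions no share under 0.1 is possible. HY5-SRDX libraries come from set 1 only, while HY5ox and HY5-VP16 hold libraries of set 1 and of other sets. These counts thus compare set 1 with other sets as well, but only in part. For HY5ox and HY5-SRDX the division that follows the sets, set 1 against sets 2 and 3, gave a sum of 870. For HY5-VP16 and HY5-SRDX no division into groups of these sizes follows the sets. Leaving out HY5-SRDX replicate 1 or 2 changed the 4 counts to 1710 or 2339, 2467 or 6919, 458 or 868, and 2646 or 7182. Without HY5ox replicate 1 the 1325 became 2019, without HY5ox replicate 2 the 881 became 1637, without HY5-VP16 replicate 2 the 1386 became 2412, and without HY5-VP16 replicate 3 the 234 became 933.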

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

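Tests of background regions, of the repression domain, of the shared control, of weak enrichment, of transgene copies and of other divisions of the libraries were chosen only after the result was seen. Of 12 measures compared over the 8 libraries taken as 1 kind, 4 had a library far from the rest, where chance gives about 1 in 20. HY5-SRDX replicate 1 stood apart in its share of peaks in promoters (51.3%), in its share of peaks in neither a promoter nor a gene body (18.4%) and in the median share of its 1000 strongest peaks found in another library (53.6%). HY5-VP16 replicate 3 stood apart in the median share of its 1000 weakest peaks found in another library (75.7%). It listed only 2958 peaks, so its 1000 weakest reached further up its list than those of the other libraries, and this measure does not compare like parts.

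HY5-SRDX replicate 1 listed the most peaks and shared the smallest part of them, 26.6% with any other library. Its weakest peaks, the lowest 10 percent by score, were found in another library in 19.7% of cases against at most 12.2% after shifts along the chromosome. Background regions may make up much of this part without being shown to be all of it. Low sharing was not confined to the weakest peaks. The share was 56.2% for the strongest 10 percent, 31.2% for the next 10 percent and 22.4% in part 5 of 10. Of its 15758 peaks in none of the HY5ox and HY5-VP16 libraries, 4.52% were in HY5-SRDX replicate 2 against at most 1.82% after shifts, which sites bound with the repression domain could give. Regions raised by the control shared in set 1 would give the same, and its remaining peaks exceeded the highest shift in 4 of 4 partners of set 1 and in 0 of 3 of sets 2 and 3. The set 1 partners without the repression domain had rates of 1.43% in HY5ox replicate 1, 1.03% in HY5-VP16 replicate 1 and 2.94% in HY5-VP16 replicate 2. Their highest shifts were 1.13%, 0.715% and 1.73%. The rate stood further above its shifts in HY5-SRDX replicate 2, but that rests on 1 library. A part from the domain beside that of the set was thus neither shown nor excluded.

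HY5-VP16 replicate 3 listed few peaks, and 3631 of its 3643 genes were also in HY5ox replicate 3 (log2 odds ratio 9.90). Weak enrichment that leaves the strongest sites could give this: the peaks it shared had a median percentile of at most 19.8 in the 5 other HY5ox and HY5-VP16 libraries. Its peak ranks correlated best with HY5ox replicate 3 (Spearman rho 0.88, across 1990 peaks, which are not independent replicates) then with HY5ox replicates 2 and 1 of the other sets (0.76 and 0.69) and least with HY5-VP16 replicates 1 and 2 (0.65 and 0.62), which carry-over from HY5ox replicate 3 may give, while a common set names only the first of these. Sites of HY5ox replicates 1 and 2 alone were listed in 11.7% and those of HY5-VP16 replicates 1 and 2 alone in 3.23%, and with sites from set 1 alone the 2 ratios of such shares were 1.60 and 3.52, beside 1.54 and 3.29 in HY5ox replicate 2 and 1.73 and 3.32 in HY5ox replicate 3, as a HY5ox sample under this label may show. Against this, its HY5 promoter peak ranked 1 as in HY5-VP16 replicate 2, and since no other HY5-VP16 library lies outside set 1, carry-over, a wrong label and a difference of set 1 from the other sets cannot be told apart.

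A peak inside the HY5 gene was listed in 6 of 8 libraries. Extra copies of the gene in the transgene could raise such a peak in every library of a transgenic line, and HY5ox replicates 2 and 3 did not list it although they listed the promoter peak. That leaves the question open, because an unlisted peak may lie under the caller's threshold and these libraries belong to sets 2 and 3. No biological explanation was tested for this peak or for HY5-VP16 replicate 3.

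For the genes in every HY5ox and no HY5-VP16 library or the reverse, 3 of the 10 divisions of the 6 libraries gave at least 416. The real division is 1 of these 3, and 675 was the highest other. With 10 divisions no share under 0.05 is possible. The division that follows the sets, set 1 against sets 2 and 3, gave 535.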

How the results depend on the processing

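The alternatives that combine the odds ratio with a block, take equal top peaks with the authors' assignment, leave out HY5-SRDX library 1 together with HY5-VP16 library 3, match lists on length or use the authors' merged peaks were chosen after seeing the data. Of the results that answer a comparison, 302 alternative values kept their direction and their side of the threshold, or stayed within 1.5 times for counts, while 12 passed the threshold, 80 counts moved and 11 changed sign. For these changes the cause was not tested, except that for counts of genes in every library fewer peaks give fewer genes, and leaving out a library gives more, by construction. The 302 include values that could not differ, so their number does not measure how stable the results are. Leaving out a library of the third construct leaves a comparison of 2 constructs as it was. The -6536 peaks of HY5ox minus HY5-SRDX, for example, stayed without HY5-VP16 replicate 1, 2 or 3. The differences in peaks and genes could not pass the threshold either, since their smallest possible exact permutation p is 0.1. The alternatives for DNA motifs were not run. The 3 differences in promoter share and the 3 log2 odds ratios of genes shared by 2 constructs kept their direction under each alternative run for them, while their calls could hardly change, since the exact permutation p of the first cannot fall under 0.1 with these library numbers and the second lie far past the threshold. What depth limits was not tested: the deepest library, HY5-VP16 replicate 3 (56.0 M tags), listed 2958 peaks, and the shallowest, HY5ox replicate 2 (11.5 M tags), listed 7043.

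The likeness of gene lists within and between constructs (main difference 0.0467, exact permutation p = 0.0964) gave 23 alternative values. Planned ones were 9 past the threshold, 8 unchanged in call and 2 reversed, and of the added ones 3 passed and 1 did not. The difference was 0.0914 for the upper part of peaks by score, 0.143 for equal top peaks by nearest start site and 0.148 by the authors' assignment. It was 0.0949 for the share of the shorter list, 0.0954 for peaks overlapping by 1 bp, 0.0974 for centres within 100 bp and 0.109 for a reciprocal overlap of 50%. The exact permutation p of these 7 ranged from 0.00357 to 0.0214. In set 1 alone it was -0.00945, and leaving out single libraries gave -0.00194 (without HY5ox replicate 3) to 0.0948 (without HY5-VP16 replicate 2). On the log2 odds ratio it was 0.80 (exact permutation p = 0.111), with p = 0.0167 under a set block and 0.0278 under the replicate block, both added. The Jaccard test with the replicate block kept 0.0467 (exact permutation p = 0.0833), and in simulated data that blocked test found strong planted differences in 20 of 20 draws. Under the replicate block the peak differences were 1439, -6846 and -5146, in tests with too few libraries to pass the threshold. The numbers do not pair the libraries: the mean log2 odds ratio of same-numbered against other libraries was 2.71 and 3.25 for number 1, 3.34 and 3.48 for number 2, and 9.90 and 3.80 for number 3, which is 1 pair.

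Likeness within sets reversed to -0.0567 and -0.0598 for equal top peaks (nearest start site, authors' assignment), -0.0634 for the share of the shorter list and -0.39 on the log2 odds ratio, and ranged from -0.0225 (without HY5-VP16 replicate 3) to 0.125 (without HY5ox replicate 3). HY5ox minus HY5-VP16 was -1390 peaks and -245.2 genes without HY5-SRDX library 1 and HY5-VP16 library 3. Without single libraries it ranged from -1390 to 3819 peaks and -245.2 to 4507 genes, the lowest without HY5-VP16 replicate 3 and the highest without HY5-VP16 replicate 2.

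Counts of genes in every library are given for HY5ox, HY5-VP16, HY5-SRDX and all 8 in turn. The upper part of peaks by score gave 3935, 1705, 3282 and 863. Equal top peaks gave 1773, 1345, 964 and 404 by nearest start site and 2608, 1911, 1247 and 575 by the authors' assignment. Genes in at least 2 libraries numbered 11339, 8557 and, for the last, 4177. Without both doubted libraries the last 3 were 8183, 11932 and 4318, and the authors' merged peaks gave 1272. Without single libraries the last 3 ranged from 3145 to 8183, 7646 to 16408 and 1915 to 3192, the highest without HY5-VP16 replicate 3, HY5-SRDX replicate 2 and HY5-VP16 replicate 3.

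Construct-specific counts moved as follows, and the text above names the libraries behind the ranges. HY5ox without HY5-VP16 was 269 (upper part), 80 and 110 (equal top peaks), 1411 (at least 2 libraries), 1439 (at most 1 of the other) and 416 to 1056 (single libraries left out). HY5-VP16 without HY5ox was 2 (nearest start site), 45 and 46 (equal top), 386 (both doubted libraries out), 390 (at least 2), 13 (at most 1) and 0 to 386 (single). HY5ox without HY5-SRDX was 1710 (both out), 1953 (at least 2), 3168 (at most 1) and 881 to 2339 (single). HY5-SRDX without HY5ox was 755 (upper), 261 and 306 (equal top), 2467 (both out), 2387 (at most 1) and 1325 to 6919 (single). HY5-VP16 without HY5-SRDX was 439 and 637 (equal top), 1893 (both out), 1017 (at least 2), 1092 (at most 1) and 234 to 933 (single). HY5-SRDX without HY5-VP16 was 612 (upper), 174 and 215 (equal top), 2693 (both out), 3002 (at most 1) and 1386 to 7182 (single).

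Numbers of lists called moved to 4 in HY5-VP16 (equal top, authors' assignment), to 3 in HY5-SRDX (equal top by nearest start site, protein-coding background, length-matched lists; 3 without HY5-SRDX replicate 2 to 7 without HY5-SRDX replicate 1) and, in all 8 libraries, to 2 (equal top, nearest start site) and 3 (equal top by the authors' assignment, both other backgrounds, length-matched lists). Among single lists 611 alternative log2 odds ratios kept their call, 45 lost it, 22 gained one and 42 changed sign, none of these past the threshold. In 29 of the 42 no member was bound in at least 1 of the settings, 18 with the main choice and 22 with the alternative, some with both. Where none was bound with both, the 0.5 added to each cell alone set the sign, and these are no change of direction in binding. Where none was bound with only the main choice or only the alternative, the share bound did change. Antenna genes in HY5-VP16, for example, had 0 of 18 bound (log2 odds ratio -1.71) and 4 without HY5-VP16 replicate 3 (0.20). Among single libraries, leaving out HY5-VP16 replicate 3, HY5-SRDX replicate 1 or HY5-SRDX replicate 2 changed a sign, and leaving out the other 5 changed none. For shade and elongation genes they were -0.38 and -0.97 in HY5ox (equal top), 0.042 (equal top) and 0.30 (both out; -1.35 to 0.30 single) in HY5-VP16, and -0.21 to 1.78 in HY5-SRDX (single). In all 8 they were 0.70 (upper), 0.11 (nearest start site), 1.83 and 1.3 (equal top) and 0.78 (both out). For antenna and Rubisco genes they were 0.20 in HY5-VP16 (both out; -1.80 to 0.20 single), 0.080 and 1.36 (equal top) and 0.21 (both out; -0.19 to 0.21 single) in HY5-SRDX, and 0.25 (upper), 1.37 and 0.85 (equal top) and 0.26 (both out) in all 8. For seed and flower genes they were 0.51 in HY5ox (equal top). In HY5-VP16 they were -0.91 (nearest start site), -0.16 and -0.69 (equal top), -1.39 (both out), -0.22 and -0.12 (protein-coding and listed-gene background; -1.39 to 0.22 single). In HY5-SRDX they were -1.53 (upper) and -0.053 (equal top), and in all 8 0.50 (upper), 1.63 and 1.1 (equal top) and -1.49 to 0.60 (single). Pigment genes gave -0.16 in HY5-VP16 and -0.053 in HY5-SRDX (equal top), flavonoid genes -0.28 (upper) and -0.068 (equal top) in HY5-SRDX, and hormone genes -0.23 and -0.24 (other backgrounds; -0.37 to 1.94 single) in HY5-SRDX. Of 89 named genes, 16 moved by upper part, 20 by nearest start site and 24 by equal top peaks.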

Other observations

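Gene families outside the fixed lists were tested after the data were seen, 84 families of at least 15 members in 3 target sets, with Fisher's exact tests and Benjamini-Hochberg adjustment. Genes of WRKY transcription factors, many of which act in defence, were bound in all 8 libraries in 15 of 67 cases, against 6.54% of other protein-coding genes (log2 odds ratio 2.08, adjusted p = 0.0059 by Fisher's exact test). Genes of CIPK kinases, partners of calcium sensors, were HY5ox targets in 13 of 21 cases, against 23.5% (2.37, adjusted p = 0.0161 by Fisher's exact test). In the 779 genes listed in both HY5-SRDX libraries and in no other, CPK calcium-dependent kinase genes held 6 of 29 members, against 2.55% (3.40, adjusted p = 0.0102 by Fisher's exact test). No other family passed in these sets, and both HY5-SRDX libraries belong to set 1. The gene count of 779 was near that of another pair, since HY5-SRDX replicate 1 alone shared 721 genes with HY5-VP16 replicate 2 that no other library listed. With HY5ox replicate 1 that number was 451. In peaks the HY5-SRDX pair stood further apart. Of the HY5-SRDX replicate 1 peaks, 712 were shared with HY5-SRDX replicate 2 only, 455 with HY5-VP16 replicate 2 only and 218 with HY5ox replicate 1 only. Among its 1000 strongest peaks these numbers were 38, 16 and 2.

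Pseudogenes were listed in 1089 of 3917 cases (27.8%) in HY5-SRDX replicate 1 and in 0.919% to 5.999% in the other 7 libraries. The other 6 libraries shared 2877 genes, of which 2473 were in HY5-SRDX replicate 2, 2114 in HY5-SRDX replicate 1 and 203 in neither.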
